A study of Mus musculus with 2 samples.

How the data were processed

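Gene expression was measured by RNA sequencing in mouse bone marrow mesenchymal stem/progenitor cells (MSPC), stromal cells that can form bone, cartilage and fat and that line the niche of blood stem cells. Cells came from Nestin-Cre mice that were either Ptpn11+/+ (control) or Ptpn11E76K/+ (mutant). Ptpn11 encodes SHP2, a phosphatase that acts in RAS-ERK signalling, and E76K is an activating amino acid change. Per the labels' protocols, cells negative for the blood marker CD45, the erythroid marker Ter-119 and the endothelial marker CD31 and positive for CD140 and Sca-1 were sorted from marrow, and polyadenylated RNA was enriched with an oligo-dT kit. The labels list 1 sample per genotype. The series' design text speaks of 2 replicates, but the table analysed here holds 1 column per genotype, and whether a column pools animals or runs is not given in the sources used here.

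The authors deposited a table of raw read counts, which are whole numbers that were not normalized, for 35275 Ensembl gene identifiers. CASAVA, TopHat, edgeR and the genome build mm9 are named in the submitters' processing notes without versions. The read counter, the annotation release and the strand setting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore be shared between them. No row was blank or a summary line, and no sample column was left unused. A gene symbol was found for 34490 identifiers, and the other 785 were kept under their identifier. The symbols come from the supplied gene name table, and transcript lengths and GC content from the longest transcript per gene of GENCODE M21. That annotation is on another genome build than the submitters name, so no coordinates are given.

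The control library held 22328659 counts and the mutant library 18010963. Library totals were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3 (1.0358 for the control and 0.9654 for the mutant). Levels in CPM, the usual scaling of counts to library size, use these scaled totals. Pairs of counts are given for control and mutant in that order and are not scaled. With 1 library per genotype no spread between animals can be estimated, so no test between genotypes was run and no p-value is given. Each fold is the ratio of the mutant library to the control library, or its inverse where a gene is given as lower. It has a 95% exact Clopper-Pearson interval from the split of the gene's counts, computed in SciPy 1.17.1. These intervals, and all floors, cover counting error only and compare these libraries, not the genotypes. Genes with at least 20 counts over both libraries were called measured. A measured gene was called higher or lower when its whole interval lay beyond 2-fold. A gene at 0 counts in one library was set to a floor of 3 counts in that library, which gives the folds written as at least. This floor leaves out the counting error of the other library, so the exact lower bound is smaller (83.35 against 103 for Ccl3). The interval of the log2 ratio had a median width of 2.75 for genes with 20 to 39 counts and of 0.233 for the 6852 genes with 1000 or more counts.

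A total of 37 gene lists (pathways, lineages, markers of other cells and signs of RNA quality) were fixed before the data were examined, as were the rules for calls, for named genes and for most alternative settings. Lists with at least 5 measured members are described by the median log2 ratio of those members (prior count of 0.5 per library), an order-statistic interval of that median over genes, and its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Random lists were drawn gene by gene with replacement. Genes of a pathway vary together, so these percentiles describe the libraries and are not tests. The named genes are Ptpn11 and Ccl3, the 12 genes per direction whose interval bound lay farthest from no difference (leaving out gene models without a proper symbol), the leading members of each list, the markers of the sort with Nes, the 5 most abundant genes per library and the sex-linked genes. Other list members given with their counts, and the genes and lists first named in the closing section, were chosen after their values were seen, except 67 further myeloid genes that were fixed before theirs were seen. Some genes that the rule names are not reported here.

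The procedure was tested on simulated pairs of libraries drawn from the real means and depths with counting noise only, with 13135 genes measured and 200 genes changed. The intervals held the true ratio for 95.6% of genes, and 0 unchanged genes were called. The rule called 4.08% of genes changed by 2-fold, 93.9% of those changed by 4-fold, 98.0% of those changed by 8-fold and 100% of those changed by 16-fold, so it leaves out most genes near its threshold. Alternatives were total counts, DESeq2 1.42.0 size factors, upper-quartile factors, other count minimums, thresholds, interval levels and prior counts, and lists without shared members. After the data had been seen, a correction was added that removes lowess trends (statsmodels 0.14.6, span 0.3, genes with 100 or more counts) of the log2 ratio over transcript length and GC content.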

Results

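Polyadenylated RNA was sequenced from sorted bone marrow MSPC of Ptpn11+/+ mice (control, 1 library) and of Ptpn11E76K/+ mice (mutant, 1 library). The comparison asks how the transcriptome of MSPC differs when one Ptpn11 allele carries the activating change. The control library held 22328659 counts over 17887 detected genes and the mutant library 18010963 counts over 17185. Fn1, which encodes the matrix protein fibronectin, was the most abundant gene in both, with 2.74% of counts in the control (95% exact binomial interval 2.73 to 2.75) and 1.5% in the mutant (1.49 to 1.5). Thbs1, Vim, Flna and Eef1a1 followed in the control, and Col1a1, Eef1a1 and Actb were among the next in the mutant. There are no replicates, so every difference below is one between 2 libraries and has no replicate check.

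Ptpn11 itself had 5958 counts in the control and 5039 in the mutant library, which was 1.12-fold higher in the mutant after scaling (95% counting interval 1.08 to 1.17). A gene-level count does not tell the mutant allele from the normal one, so this value does not check the genotype. Of the genes behind the sort, Ptprc (CD45) had 1 and 12 counts in control and mutant, and Pecam1 (CD31) had 5 and 2. Of the CD140 genes, Pdgfra was 1.15-fold higher (1.08 to 1.23) and Pdgfrb 1.23-fold lower (1.18 to 1.28) in the mutant. Ly6a, the gene of Sca-1, was 2.67-fold lower (2.44 to 2.93), and Nes, which encodes nestin, was 2.76-fold higher (2.67 to 2.86). Xist had 21878 and 9051 counts, while the Y-linked genes Ddx3y, Eif2s3y and Kdm5d had 0 in both libraries, which allows up to 0.13 CPM in the control and 0.173 CPM in the mutant, and Uty had 0 and 2.

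Across the transcriptome, 917 genes were higher and 1090 lower in the mutant library with their whole counting interval beyond 2-fold, together 15.3% of the 13142 measured genes. Of the calls, 45.7% were higher, and this share was 35.1% when the most abundant genes were left out of the library totals. Beyond 4-fold, 223 genes were higher and 265 lower. Ranked by the bound of the interval, the first gene was Igsf23, an immunoglobulin superfamily member, with 3 counts in the control and 1029 in the mutant, a ratio of 456 (156 to 2220). Lce1g, a cornified envelope gene of the epidermis, had 1 and 619 counts, a ratio of 823 (147 to 32570). Serpinb2, which encodes a serpin, was 144-fold higher (89.6 to 248). F11r, which encodes a tight junction protein, was 225-fold higher (87.3 to 826), and Tmem171 157-fold higher (71.8 to 429). The neuronal ubiquitin hydrolase gene Uchl1 was 116-fold, the collagen-processing cofactor gene Pcolce2 69.1-fold, the matrix gene Npnt 56.8-fold and the microtubule gene Map2 52.9-fold higher. C3ar1, the complement C3a receptor gene, had 2 and 215 counts, a ratio of 143 (39.1 to 1190). Sprr2h, another cornified envelope gene, had 0 and 99, at least 43.9-fold higher at the floor of 3 counts (exact lower bound 35.0).

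In the other direction, the WNT ligand gene Wnt16 had 5659 counts in the control and 16 in the mutant, a 266-fold lower level (164 to 466). Stox2 (569 and 0 counts) was at least 143-fold lower, the channel gene family member Ano3 (340 and 0) at least 85.2-fold, the imprinted gene Peg3 (335 and 0) at least 83.95-fold, and Npy2r, a neuropeptide Y receptor gene (218 and 0), at least 54.6-fold lower. These folds are at the floor of 3 counts, and the exact lower bounds were 115.6, 68.9, 67.9 and 44.05 in that order. Hpgd, whose enzyme inactivates prostaglandins, had 161 and 0 counts and was at least 40.3-fold lower at that floor (exact lower bound 32.4). Eda, which encodes ectodysplasin, was 103-fold lower (49.95 to 258). Pygo1, which encodes a WNT co-activator, was 55.4-fold lower, Csmd1 68.6-fold lower, and Wscd2 (318 and 3 counts) 79.7-fold lower (27.0 to 389). Cdkn2a, the gene of the cell cycle inhibitor p16 and of ARF, was 38.6-fold lower (25.4 to 61.9). The pseudogene Nlrp5-ps had 122 and 0 counts, but reads of pseudogenes can be shared with related genes.

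**Figure D1:**
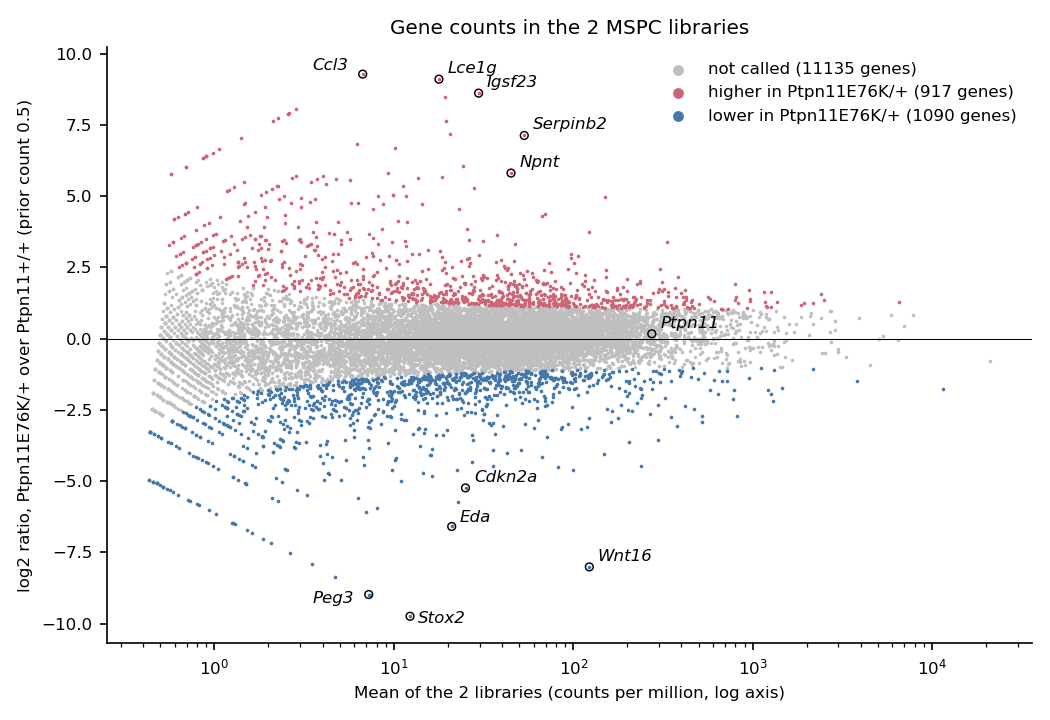
Log2 ratio of the Ptpn11E76K/+ library over the Ptpn11+/+ library (prior count 0.5 per library) against the mean level of the libraries in CPM on a log axis, for the 13142 measured genes, 1 point per gene, with 1 library per genotype. Red points are the 917 genes called higher and blue points the 1090 called lower in the mutant library; circled genes are named in the text, and Ptpn11 lies close to 0 with a log2 ratio of 0.17.

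Among CC chemokines, which attract leukocytes, Ccl3 had 0 counts in the control and 233 in the mutant library, at least 103-fold higher at the floor of 3 counts, with an exact lower bound of 83.35. Ccl4 (12 and 97 counts) was 10.8-fold higher (5.88 to 21.5), Ccl12 (34 and 258) 10.1-fold (7.04 to 14.9) and Ccl17 (5 and 28) 7.45-fold (2.84 to 24.7). The other 8 of the 12 measured members were not called. Ccl2 (1002 and 773 counts) was 1.03-fold higher after scaling (0.93 to 1.13) and Ccl7 1.66-fold higher (1.46 to 1.89). The list's median log2 ratio was 0.11, at percentile 84.9 of random lists, and it was -0.02 when the most abundant genes were left out of the totals, so the list did not stand apart as a whole. In absolute terms Ccl3 reached 13.4 CPM in the mutant library. Markers of myeloid cells were higher in the same library. Of 20 monocyte and macrophage markers 10 were measured, and of these 8 were called higher and 0 lower (median log2 ratio 4.05, or 3.57 with zeros at the floor, percentile 100), including Lyz2 (11 and 276 counts), Ctss (0 and 34), C1qa (0 and 24) and Mpeg1 (5 and 62), while Csf1r was present in both libraries (149 and 229). Lyz2, Ctss, C1qa and Mpeg1 passed the minimum of 20 counts only through the mutant library, which favours this direction. With no minimum count the list median was again 4.05, at percentile 100. Cd14 was not called, which left 7, with total counts, with totals without the most abundant genes, and without the trends over transcript length and GC content.

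Of the CXC and other chemokines, 5 were measured. Ppbp was 6.35-fold higher (5.37 to 7.54) and Cxcl12, which holds blood stem cells in the marrow, 3.39-fold lower (3.24 to 3.55), with a list median of 0.23 at percentile 72.3. Of the 9 measured inflammatory cytokine genes, 3 were called higher. The interleukin-1 receptor antagonist gene Il1rn was 42.2-fold higher (23.9 to 82.5), Lif 8.16-fold and Tgfb1 4.23-fold higher. Il18 was 4.64-fold lower (2.97 to 7.56) and Il15 5.26-fold lower (2.86 to 10.6). This list had a median of -0.11 but a mean of 0.61, and lay at percentile 55.5. With no minimum count its median was 1.34, at percentile 99.91. Il1b had 0 and 1 counts and Tnf had 0 and 4. The myeloid markers above were higher in the same library as Il1rn and Lif.

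Of 23 measured transcriptional targets of ERK signalling, 8 were called higher in the mutant library, 2 lower and 13 not called, with a median log2 ratio of 0.97 (interval over genes 0.22 to 1.60) at percentile 100. The ERK phosphatase gene Dusp5 was 12.4-fold higher (10.4 to 15), the AP-1 gene Fosl1 7.86-fold (7.15 to 8.65), Myc 4.90-fold (4.42 to 5.44) and the ETS factor gene Etv4 4.47-fold (3.90 to 5.15). Epha2, Phlda1, Ier3 and Dusp2 were the other genes called higher. The feedback inhibitor gene Spry1 was 3.38-fold lower (2.93 to 3.92) and Epha4 was also called lower, but not with the length and GC trends removed. Egr1 had 3618 and 3164 counts before scaling and was not called. The median was 0.90 with the trends over transcript length and GC content removed.

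Components of the RAS-ERK pathway themselves were mostly uncalled (18 of 20), with a median of -0.04 at percentile 15.7, which was 0.13 without the length and GC trends. Hras was 2.39-fold higher (2.23 to 2.57) and Araf 2.42-fold lower (2.28 to 2.58), but without these trends Hras was not called (2.13-fold, lower bound 1.99). Immediate early genes, which also respond to cell dissociation, had 5 of 20 members called higher and 0 lower (median 0.45, percentile 98.0), with Nr4a1 7.47-fold and Atf3 4.50-fold higher. Without the length and GC trends this list lay at percentile 91.1, and Jun was called neither there nor with total counts, upper-quartile factors or totals without the most abundant genes, which left 4. In the NF-kB list, 3 of 16 were called higher and 0 lower (median 0.50, percentile 99). Ptgs2, which encodes the prostaglandin synthase COX-2, was 13.5-fold higher (12.1 to 15), Traf1 3.06-fold and Tnfaip2 2.35-fold higher. Icam1 was called lower without the length and GC trends (3.15-fold), where the interval of the median over genes was -0.0936 to 0.816, and with totals without the most abundant genes (3.03-fold).

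Of 27 measured cell cycle genes, 7 were called higher in the mutant library, 0 lower and 20 not called, with a median log2 ratio of 0.76 (0.42 to 1.05) at percentile 99.99. The calls were 4 under total-count scaling, 4 without the length and GC trends and 3 when the most abundant genes were left out of the totals. The ribonucleotide reductase gene Rrm2 was 2.74-fold higher (2.64 to 2.83), and the replication helicase genes Mcm5 and Mcm3 were 2.57-fold and 2.55-fold higher. The proliferation marker gene Mki67 was at 484 CPM in both libraries. In the p53 and senescence list, 7 of 15 genes were called lower and 0 higher (median -0.89, interval -1.88 to -0.32, percentile 0.0). Besides Cdkn2a, Trp53inp1 was 15.2-fold lower (12.5 to 18.5), Eda2r 4.55-fold, Cdkn2b 3.69-fold, Sesn1 2.93-fold, Ccng1 2.86-fold and Gdf15 2.22-fold lower. Cdkn1a, the gene of the cell cycle inhibitor p21, had 5189 and 3496 counts and was not called. Of 20 hypoxia and glycolysis genes, the glycolytic genes Pkm (2.53-fold), Gapdh (2.36-fold) and Eno1 (2.25-fold) were higher, while Bnip3 (2.84-fold) and Pdk1 (2.5-fold) were lower (median 0.54, percentile 97.53). The interval of this median over genes was -0.234 to 0.927, which includes 0. That list lay at percentile 97.36 with DESeq2 size factors and at 91.5 without the length and GC trends, where Eno1 was not called (1.89-fold).

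Of 19 measured interferon-stimulated genes, 12 were called lower in the mutant library and 0 higher, with a median log2 ratio of -1.85 (-3.46 to -0.91) at percentile 0.0. Ifit3 was 15.3-fold lower (12.1 to 19.5), but its reads can be shared with the near-identical Ifit3b. Ifit1 was 18.4-fold lower (8.72 to 46.4), Gbp3 17.5-fold (6.60 to 65.5), Gbp2 7.37-fold (5.09 to 11), and Irf7, the transcription factor gene of the response, 10.4-fold lower (4.24 to 33.0). Stat2 and Irf9, which encode partners in the interferon-activated transcription factor complex, were 3.62-fold and 3.35-fold lower. Ifit2 (923 and 611 counts) and Ifih1 (79 and 77) were not called. The class II antigen gene H2-Ab1 had 58 and 0 counts, at least 14.5-fold lower at the floor of 3 counts, and was 1 of only 4 measured genes of its list.

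MSPC identity genes went both ways, with 6 of 17 called higher and 4 lower (median 0.20, percentile 67.9). The median was 0.453 without the length and GC trends, at percentile 96.34, and 0.0999 with total counts. The BMP antagonist gene Grem1 was 5.35-fold higher (4.42 to 6.51), Mcam 5.46-fold (3.97 to 7.65), Cd44 3.39-fold and Thy1 2.57-fold higher, but Thy1 was not called without the length and GC trends or when the most abundant genes were left out of the totals. Ebf3 was 4.84-fold lower (3.10 to 7.87) and the limb mesenchyme factor gene Prrx1 2.75-fold lower. Lepr, a marker of perivascular marrow stroma, had only 7 and 4 counts. Among 15 measured niche factors of blood stem cells, 2 were called higher and 4 lower (median -0.35, percentile 5.27). Kitl, which encodes stem cell factor, was 4.33-fold higher (3.77 to 4.98). Angpt1 was 13.1-fold lower (8.59 to 20.9), Ptn 8.0-fold lower (7.18 to 8.94) and the osteopontin gene Spp1 3.34-fold lower (3.27 to 3.41). Csf1 was abundant in both libraries, with 65215 and 45459 counts.

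In the chondrocyte list, 7 of 13 genes were called lower and 1 higher (median -1.30, interval -2.01 to -0.42, percentile 0.02). Without the length and GC trends 5 were called lower, and with no minimum count the median was -0.683. Cnmd, which encodes chondromodulin, had 99 and 2 counts and was 37.2-fold lower (10.03 to 312). Comp was 5.16-fold lower (4.42 to 6.06), Cilp 4.04-fold and the cartilage master regulator gene Sox9 2.66-fold lower (2.45 to 2.90), while Hapln1 was 7.98-fold higher (5.20 to 12.7). In the fibroblast matrix list, 4 of 17 were called lower and 2 higher (median -0.69, percentile 0.015). Dcn was 5.59-fold lower (5.36 to 5.83), Thbs1 3.43-fold and Bgn 2.82-fold lower, and the microfibril gene Mfap5 was 11.7-fold higher (7.89 to 17.95). Of 8 measured hedgehog pathway genes, 3 were called lower and 0 higher (median -1.12, percentile 0.06). Hhip (103 and 1 counts) was 77.4-fold lower (13.6 to 3088), Gas1 6.79-fold lower (6.45 to 7.16) and Cdon 2.79-fold lower. Matrix proteases and inhibitors were split, with 3 of 16 higher, among them Mmp13 (4.64-fold), and 3 lower, among them Adamts1 (6.61-fold; median -0.40, percentile 2.77). That list lay outside the middle 95% of random lists without the length and GC trends (percentile 0.31) and with 5 expression bins (1.76).

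Osteoblast genes had 3 of 13 members called lower and 0 higher, but the median was 0.24 and the mean -0.42 (percentile 78.3). Postn was 17.99-fold lower (15.02 to 21.7) and Omd 3.39-fold lower, while Col1a1 was 1.75-fold and Col1a2 1.94-fold higher without being called, although Col1a2 was called without the length and GC trends (2.03-fold). Adipocyte genes had 2 of 11 called higher and 2 lower (median 0.43, percentile 94.7). Zfp423, a preadipocyte factor gene, had 110 and 3 counts and was 27.6-fold lower (9.19 to 136), and the lipid-binding protein gene Fabp4 was 3.0-fold higher (2.34 to 3.86). Of 11 WNT pathway genes, 3 were called higher and 2 lower (median 1.06, percentile 99.9), but the interval over genes was -1.8 to 4.42, which includes 0. Lgr6 was 53.9-fold higher (20.6 to 200.1), Lef1 had 3 and 56 counts, a ratio of 24.8 (8.07 to 124), and Wif1 was 24.96-fold lower (17.4 to 37.2). The third gene called higher, Axin2 (26 and 63 counts), was called neither without the length and GC trends nor with total counts, upper-quartile factors or totals without the most abundant genes. That list lay within the middle 95% of random lists at a minimum of 100 counts (percentile 73.9) and with no minimum (90.5), with a median of 0.197 in both. TGF-beta and BMP targets (2 of 14 higher, 1 lower, percentile 73.0) and Notch pathway genes (1 of 8 higher, 1 lower, percentile 85.3) did not stand apart. In the former, Skil was 2.43-fold higher and Tgfbi 5.13-fold lower.

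Of 19 pan-haematopoietic genes, 8 were measured, and 4 of these were called higher and 0 lower (median 3.71, or 2.61 with zeros at the floor, percentile 100). The interval of the median over genes was -0.399 to 7.04, which includes 0. Itgb2 had 0 and 49 counts, Lcp1 2 and 76, Laptm5 0 and 31, and Tyrobp 0 and 20. These genes passed the minimum of 20 counts only through the mutant library, so being measured already set their direction. With no minimum count the list median was 3.47, at percentile 100. Arhgdib, by far the most abundant of the list (5148 and 2934 counts), was lower in the mutant without being called. Neutrophil, erythroid, B cell, and T and NK cell lists had 1, 1, 1 and 0 measured genes, and the osteoclast and skeletal muscle lists 2 and 4. The B cell adaptor gene Blnk (0 and 89 counts) and the enolase gene Eno3 (149 and 2220) were higher in the mutant. Of 7 measured endothelial genes, 4 were called higher and 0 lower (median 2.02, percentile 99.8), but the interval over genes was -0.359 to 4.74, which includes 0. The list was led by the VEGF receptor gene Flt1 (14 and 290 counts) and by Cd34 (578 and 1765), whereas Cdh5 had 0 and 3 counts. Pericyte and smooth muscle genes had 3 of 10 higher and 2 lower (percentile 94.8, or 99.77 at a minimum of 100 counts), with Tagln 3.73-fold higher (3.63 to 3.83) and Rgs5 at 34 and 1 counts. Without the length and GC trends the median of the pericyte list went from 0.539 to 0.257, at percentile 76.59. Megakaryocyte (percentile 58.4) and Schwann and neural lists (percentile 26.9, median -0.38 but mean 0.19, and a median of 0.06 with no minimum count) did not stand apart. The nuclear RNAs Malat1 and Neat1 were 1.70-fold and 1.57-fold lower in the mutant.

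Altogether 28 lists could be described, and 14 lay outside the middle 95% of random lists, 9 above and 5 below, where 1.4 random lists would do so on average. That average holds for genes drawn independently. Genes of one list vary together and some are in more than one list, so the excess is not a test. Across genes, the log2 ratio went down with transcript length (Spearman's rho -0.234 over 11135 genes, which are not independent replicates) and up with GC content (rho 0.173). Its median was 0.36 in the eighth of genes with the shortest transcripts and -0.29 in the eighth with the longest. With these trends removed, the medians of the interferon (-1.83), p53 (-1.10), chondrocyte (-1.0), hedgehog (-0.83), fibroblast matrix (-0.53) and cell cycle (0.74) lists kept their signs and stayed outside the middle 95% of random lists. The interval of the fibroblast matrix median over genes was then -0.883 to 0.0148, which includes 0.

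**Figure D2:**
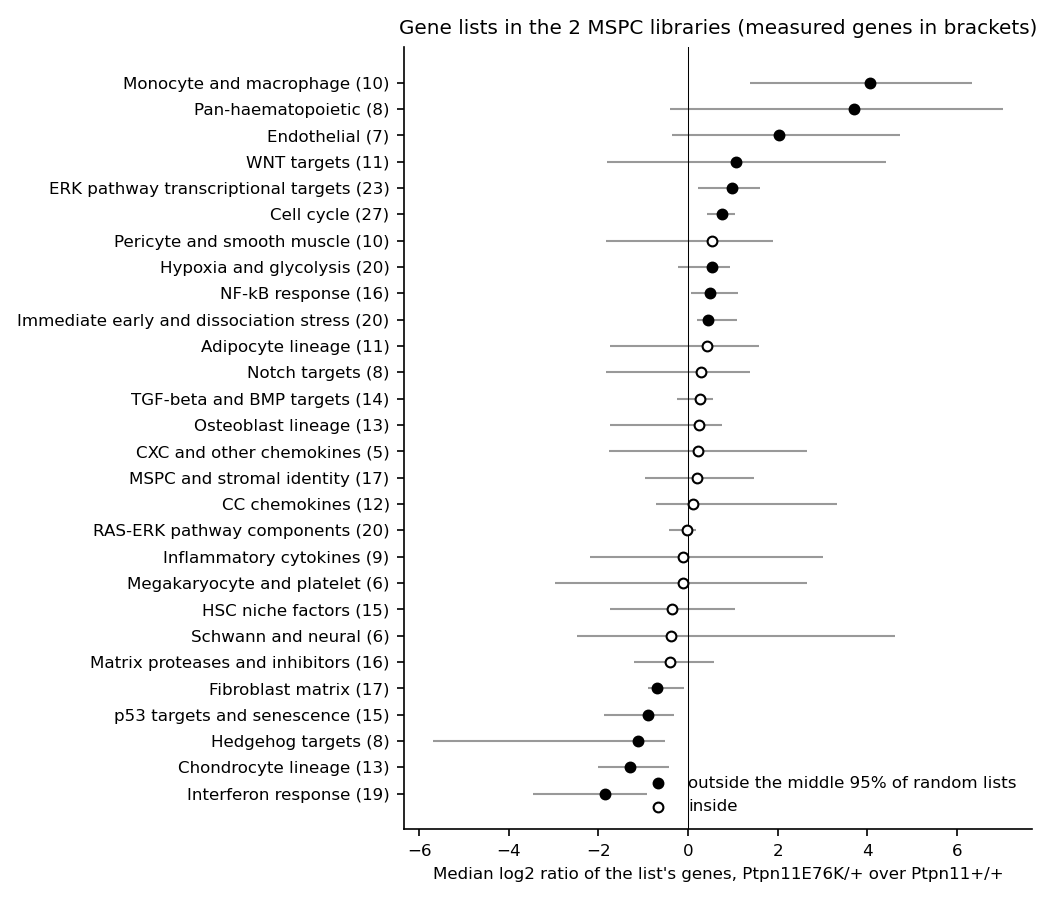
Median log2 ratio of the Ptpn11E76K/+ library over the Ptpn11+/+ library for the 28 gene lists with at least 5 measured genes (number in brackets). Points are medians, lines the 95% order-statistic intervals over genes, and filled points lie outside the middle 95% of 10000 expression-matched random lists; the interferon list is lowest at -1.85 and the monocyte and macrophage list highest at 4.05.

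**Figure D3:**
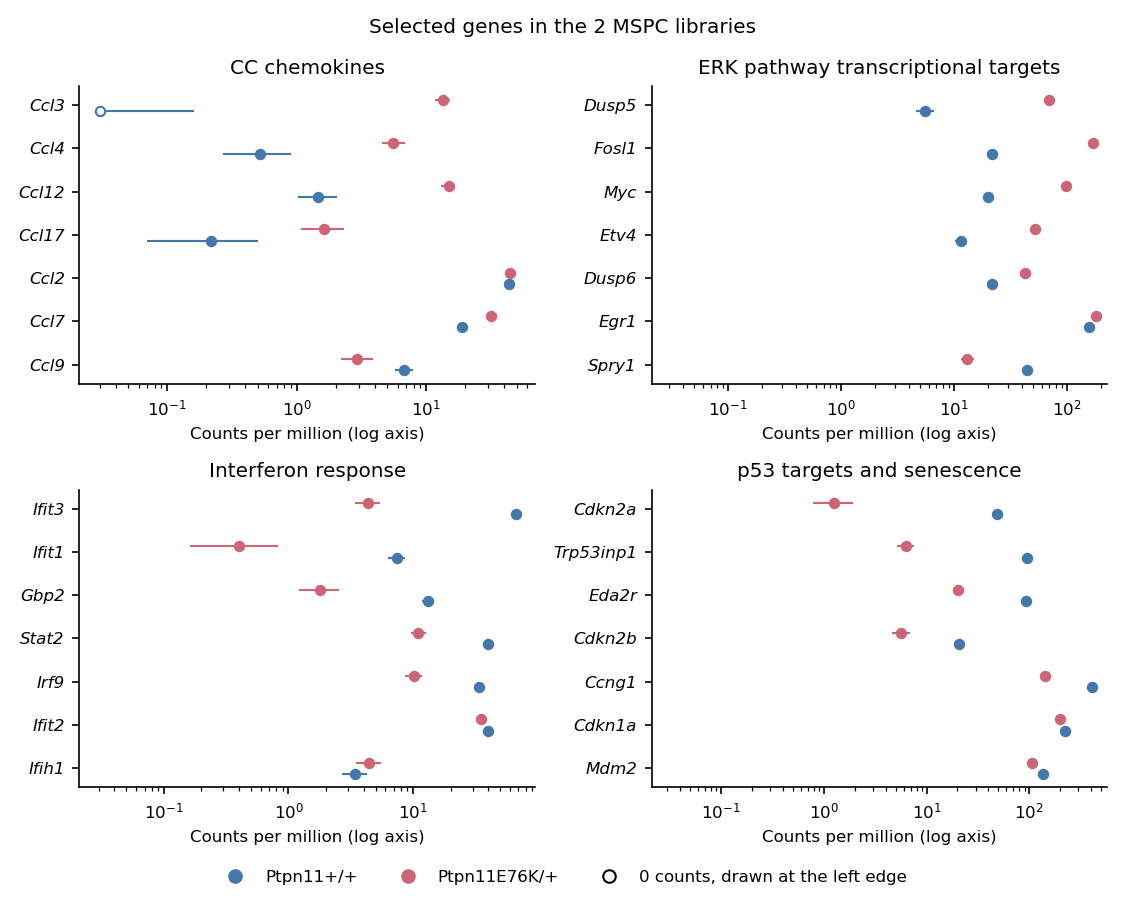
Levels in CPM on log axes for selected genes of 4 lists in the Ptpn11+/+ (blue) and Ptpn11E76K/+ (red) libraries, 1 library each, with 95% exact Poisson intervals that cover counting error only. Ccl3 has 0 counts in the control (open point at the left edge) and 13.4 CPM in the mutant, and Ifit3 and Cdkn2a are lower in the mutant by 15.3-fold and 38.6-fold.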

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

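With 1 library per genotype no replicate could be left out, and no paired analysis was possible because each genotype had a single library. The number of genes higher (917) and lower (1090) stayed within 1.5 times its value under all 3 other scalings, both other count minimums, the 99% interval, the removal of other-cell genes, totals without the most abundant genes, and the length and GC correction, which was chosen after the data had been seen. It was 1416 and 1825 when the ratio itself had to reach 2-fold, and 223 and 265 beyond 4-fold, as those rules are looser and stricter by construction. Total-count scaling moved all log2 ratios by -0.102, and totals without the most abundant genes by -0.132. The log2 ratio of Ptpn11 (0.17) was 0.068 with total counts and 0.42 with the length and GC trends removed, and the cause was not tested further. Of 28 lists, 14 lay outside the middle 95% of random lists, 11 to 15 did so under the alternatives, and 11 of the 14 did so under every one that gave a value. The exceptions were immediate early genes (inside without the length and GC trends), WNT genes (inside at 100 counts and with no minimum), and hypoxia and glycolysis genes (inside with DESeq2 size factors and without the trends). The median of the CC chemokine list ranged from -0.02 with totals without the most abundant genes to 0.46 at 100 counts, and that of the ERK targets from 0.84 to 1.04 under the same settings. At 100 counts 22 lists had 5 or more genes, so the pan-haematopoietic, macrophage and endothelial lists gave no value there, and 26 did without shared members. In the other direction, inflammatory cytokines lay outside with no minimum, pericyte genes at 100 counts, and matrix proteases without the trends and with 5 bins. The 96 alternative values of single named genes, which leave out Ptpn11, moved by less than 1.5 times. This says little, since these genes were picked for large ratios and each other scaling moves all genes by the same small amount. Of 193 alternative medians of the other lists, 32 in 14 lists moved by over 1.5 times or changed sign, although none left its wide interval over genes. The chondrocyte median went from -1.30 to -0.683 and that of WNT genes from 1.06 to 0.197 with no minimum. That of niche factors went from -0.35 to -0.63 without shared members, but to -0.229 with no minimum and to -0.17 without the trends. Notch genes went from 0.284 to 0.925 without shared members. Besides the CC chemokine median, list medians changed sign in inflammatory cytokines (1.34) and Schwann and neural genes (0.06) with no minimum count, and in RAS-ERK components (0.13) without the trends. Among list members not named so far, Col5a1, Adamts5, Ifi44 and Notch3 were no longer called lower without the trends, and Notch1 was no longer called higher with totals without the most abundant genes. Il34 and Isg15 were newly called lower and Hk2 higher without the trends, and Ptch1, Timp3 and Impact lower with total counts and, like Foxc1, Cbl and Fbln2, with totals without the most abundant genes. Depth limits low genes most: at 20 to 39 counts the interval of a log2 ratio is 2.75 wide.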

Other observations

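All tests in this part were chosen after the patterns had been seen. Those of a leak of blood cells of every kind and of a loss of Cdkn2a and Cdkn2b, with their bounds, were also chosen after their own values had been seen. The Hox, imprinted, epidermal, ribosomal protein and further myeloid genes were listed after the patterns as well. The p53, interferon, chondrocyte and blood cell lists were fixed before the data were examined. Most measured genes of the Hox B cluster, which encode position along the body axis, were lower in the mutant library. Hoxb9 had 644 counts in the control and 18 in the mutant, Hoxb6 70 and 0, Hoxb8 68 and 1, Hoxb4 60 and 0, and Hoxb5 24 and 0. Of 7 measured Hox B genes, 5 were called lower (median log2 ratio -5.1, or -3.91 with zeros at the floor, interval over genes -6.73 to 0.95). In the other clusters 0 of 9 Hox A genes and 0 of 9 Hox C genes were called lower (medians -0.37 and -0.55), Hox D had 3 measured genes, and Hoxa4 (16 and 45 counts, 3.74-fold, 2.07 to 7.09) and Hoxc13 (2.95-fold, 2.60 to 3.35) were called higher. Without the length and GC trends Hoxc6 was called lower (2.40-fold), and Hoxa4 was not called there or with total counts. Imprinted genes, of which only one parental copy is active, had 7 of 21 measured members called lower and 0 higher (median -0.98). Besides Peg3, these were H19 (687 and 80 counts), Dlk1 (381 and 43), Ndn (2602 and 460), Plagl1 (554 and 117), Cdkn1c (97 and 15) and Igf2r (5284 and 1750), the last not called without the length and GC trends (1.82-fold).

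Of 26 epidermal and epithelial genes, listed after Lce1g and Sprr2h had been seen among the leading genes, 12 were measured and 9 of these were called higher in the mutant, among them Lce1g (1 and 619 counts), Crct1 (30 and 390), S100a7a (9 and 194) and Sprr1a (2 and 92). Some core epithelial genes were close to 0 in both libraries, with Krt5 at 0 and 1 counts, Krt14 at 0 and 3, Cdh1 at 0 and 1 and Epcam at 0 and 0, and Krt10 was not called (105 and 79). Others were present: Dsp (6 and 81 counts) and Ppl (51 and 370) were called higher, and Krt19 (61 and 115) was 2.51-fold higher without being called. Trp63, a master regulator gene of the epidermis, was 14.8-fold lower (315 and 16 counts). Ribosomal protein genes, which have short transcripts, had a median log2 ratio of 0.93, with 43 of 45 above 0, and a median of 0.59 after the length and GC trends were removed.

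Myeloid cells or their RNA in the mutant sample are a candidate explanation of higher Ccl3 (0 and 233 counts), C5ar1 (13 and 334), Lyz2 (11 and 276), Ctss (0 and 34) and C1qa (0 and 24): of 67 further myeloid genes, chosen before their values were seen, 38 had 4 or more counts, and 33 of these (86.8%, 95% exact binomial interval 71.9 to 95.6) had a ratio above 1, against 39.9% of all genes in that count range. This counts signs of mostly uncalled genes: 3 were called higher and 0 lower, 19 had their interval above 1 and 2 below, and 31 (81.6%) had a ratio above 1 with total counts. A share of signs ignores amounts, and the 67 genes together had only 299 and 642 counts, with Pik3r5 at 17 and 177. It therefore cannot show whether such RNA would account for the counts of Ccl3 or C5ar1. The binomial interval treats genes as independent, but genes of one cell type vary together. Genes with fewer than 4 counts, such as Ms4a7, Clec12a and Marco with 0 in both libraries, are left out of this share. Against myeloid cells or their RNA speak the sort for CD45-negative cells, which would remove most such cells, low counts of Cd74 (1 and 4) and Aif1 (1 and 0), and Plek (55 and 12) and Tlr7 (25 and 5), which had lower levels in the mutant without being called. For a leak of blood cells of every kind, 4 of 47 neutrophil, erythroid, B, T and NK genes with 3 counts or fewer in the control had more than 3 in the mutant (8.51%, 2.37 to 20.4). Of such pan-haematopoietic and macrophage genes, 21 of 29 did (72.4%, 52.8 to 87.3), leaving out 10 seen above 3 counts in the control. The second share belongs to the pattern itself, and genes of rarer cells could stay at 3 counts or fewer. This comparison therefore does not exclude such a leak. Bulk counts do not show whether Ccl3 came from MSPC or from other cells, and an effect of the genotype on MSPC stays open.

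The median of the p53 and senescence list was below 0, and Cdkn2a was its leading gene. A trend with transcript length and GC content is argued against as the whole cause, since the median was -1.10 (interval -1.92 to -0.40) after both trends had been removed. Loss of both the Cdkn2a and Cdkn2b genes from all cells is argued against by 98 counts of Cdkn2b in the mutant library (exact Poisson lower bound 79.6). Cdkn2a had 22 counts there. These counts cannot tell whether part of the cells lost one or both genes, which was not tested. The neighbouring gene Mtap (2124 and 2710 counts) was 1.70-fold higher in the mutant after scaling (1.60 to 1.80). Trp53 itself (2416 and 3658) was 2.01-fold higher (1.91 to 2.12), and neither gene was called. The genotype, a difference between animals and cell handling remain open and untested.

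Lower interferon and chondrocyte genes were tested against the same trend with transcript length and GC content, whose source was not tested. After removal of the length and GC trends their medians were -1.83 (interval -3.69 to -1.04) and -1.0 (-2.04 to -0.11), so such a trend is unlikely to be the whole source. A different mix of stromal subtypes in each sort, a difference between animals, and the genotype remain open and untested.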
